A study of Mus musculus with 7 samples.

How the data were processed

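RNA from sorted tumour cells that carried Cd34 and Epcam was measured on 7 Affymetrix mouse arrays, 4 from carcinomas and 3 from papillomas. Per the labels' protocols, RNA was purified with a micro column kit, amplified and labelled with biotin, and the authors normalized the arrays with RMA, which corrects background, equalises the distributions of the arrays and summarises each probe set. The submitters' processing notes name RMA and affy, and their versions, the chip definition and which arrays were normalized together are not given in the sources used here. The deposited table holds log2 values from 2.72 to 14.51. The scale was read from these values, since the labels do not state it. Labels name the 430 strip version of the array, while the probe set names are those annotated for the standard design, so gene names rest on that match.

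The table holds 45101 probe sets, of which 64 are control probe sets. The platform annotation of 2016 gives exactly 1 gene symbol to 34958 probe sets and several symbols to 932, and 9211 probe sets are not listed in it and are unnamed here. For 34741 of the probe sets with 1 symbol the gene identifier was also in the RefSeq table of assembly GRCm38.p6, and that table was used for names only. Each gene was represented by its probe set with the highest mean over the 7 arrays, among probe sets with 1 symbol, which gave 18193 genes. Control probe sets were left out and dim probe sets were kept. The 10092 probe sets without a single gene gave 0 calls when tested apart from the others, with adjustment over these probe sets alone.

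Groups were taken from the tumour type in the labels. Carcinoma was compared with papilloma by limma 3.58.1 in R 4.3.3 with lmFit and eBayes, without covariates, and p-values were adjusted by the Benjamini-Hochberg method over all 18193 genes with a threshold of 0.05. Gene lists were tested with limma's camera, two-sided, with a preset correlation of 0.01, adjusted over the 27 lists, beside camera with an estimated correlation and fry, whose directional p asks whether the genes of a list move on balance one way. With an estimated correlation the smallest adjusted p was 0.953, so none of the 3 calls held, and the smallest adjusted p of fry was 0.998 for one direction and 0.946 for either direction. The lists held 572 distinct genes, of which 527 were measured, and the others are not analysed here. Of the lists, 18 describe tumour cell biology, 1 the response to cell isolation and 8 other cell types. Exact two-sided permutation tests of single genes used all 35 splits of the 7 arrays, and sign flips of the 3 pairs were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

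The design, the lists and the rule for named genes were fixed before the data were examined. The rule named Nr2f2, Cd34 and Epcam, then 14 genes in each direction, and up to 4 members per list with the largest change. The 14 genes were to be those with the largest change among genes past the threshold, with groups that did not overlap, a mean above the median gene in the higher group and a proper symbol. Since 0 genes passed, the rule filled both directions with the genes of smallest unadjusted p under the same other conditions. Naming 4 members for the called lists and 2 for the others was decided after the calls were seen. Krt5, Krt14, Krt15, Ddx58, Mx1 and the genes that describe the GFP arrays lie outside the rule and were chosen after their values were seen.

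Replicate numbers 1 and 2 and the tag GFP occur in both groups. Deviations from the group means correlated at 0.476 for the arrays numbered 1, 0.194 for those numbered 2 and 0.861 for the GFP pair, across genes, which are not independent replicates. All 3 lie above 0.1, the limit set for treating the numbers as pairs, so the fit with the replicate number as a block is given for Nr2f2 and where it changes the call of a list or a count of genes, and its values for most other genes and lists are not printed. Arrays of different numbers passed this limit too. Papilloma 1 correlated at 0.683 with carcinoma 2 and 0.207 with carcinoma 3, and papilloma 2 at 0.254 with carcinoma 1 and 0.478 with carcinoma 3. The limit therefore cannot show that the numbers mark pairs, and the block fit is given as an alternative only. Without the GFP arrays the same-numbered pairs gave 0.101 and -0.303. These correlations and the calls of the fits were first seen together.

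The procedure was tested on simulated arrays with the spread of these data over 18193 genes. With no change it called 0 genes. Among 200 genes changed by 1, 2, 3 and 4 log2 units it recovered 0%, 72%, 88.5% and 94% with all 7 arrays, and 0%, 77%, 92.5% and 99.5% without the GFP arrays. In the same runs it called 0, 4, 9 and 10 unchanged genes with all 7 arrays, and 0, 5, 14 and 12 without the GFP arrays. Of the gene lists, 1 list raised by 1 unit was called and 0 others. The simulated genes were independent, whereas the 3 lists called here had estimated correlations of 0.36, 0.54 and 0.48. That run therefore cannot show how often correlated lists are called falsely. The runs on genes also cannot show the share of real changes recovered, since 200 genes changed at once with independent noise. The median residual SD of a gene was 0.397 with all 7 arrays and 0.299 with the GFP tag as a covariate.

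Alternatives were another quantile normalization, centring of each array, a filter on dim genes, the mean of all probe sets of a gene, removal of probe sets prone to cross-hybridisation, an intensity trend with robust variance, array weights, the replicate block, the GFP tag as a covariate, removal of the GFP arrays, removal of each array in turn, single probe sets, and other thresholds. Removal of the most alike pair of arrays, carcinoma 2 and papilloma 1, was added after seeing the data. The background correction and the scan date were not varied, since they need scanner output, which is not used here.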

Results

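Gene expression was measured on Affymetrix mouse arrays in tumour cells that carried the surface antigens Cd34 and Epcam and had been isolated by flow cytometry from chemically induced skin tumours. The tumours had been raised with DMBA, a carcinogen that starts skin tumours, and TPA, a promoter of their growth. Papillomas, the benign form, gave 3 arrays, and carcinomas, the malignant form, gave 4 arrays. The title of the series names Nr2f2, a nuclear receptor, in relation to the malignant state, invasion and differentiation, so carcinoma cells were compared with papilloma cells. The sample descriptions also put Nr2f2 before the tumour type and state no genotype, so whether a change of this gene is meant, in all arrays alike, is open, and none was assumed for the Nr2f2 levels below. In each group 1 array carried the tag GFP in place of a replicate number, and the labels do not explain the tag. The labels do not say whether the arrays came from separate animals, so the p-values measure only the spread between these samples. Array medians lay between 5.38 and 5.51 on the log2 scale, and upper quartiles between 7.32 in papilloma 2 and 7.79 in papilloma 1. The number of arrays limits the precision of every value.

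The largest difference between arrays followed the GFP tag and not the tumour type. The first principal component of the gene levels held 63.8% of the variance and placed carcinoma GFP at 107.1 and papilloma GFP at 96.3, with the other 5 arrays between -48.3 and -35.5. Endothelial markers were higher in the GFP arrays by a median of 5.31 log2 units (15 of 15 genes by more than 2 units). Fibroblast markers were higher by a median of 4.05 (12 of 14 genes by more than 2 units). Kdr, a receptor for vascular growth factors, averaged 12.49 in the GFP arrays and 6.39 in the other arrays, and Cdh5, the cadherin of endothelial junctions, averaged 11.16 and 4.91. Vim, a mesenchymal intermediate filament, averaged 13.26 and 8.61, whereas Epcam, on its brightest probe set, averaged 8.94 and 11.39 and Cdh1, the epithelial cadherin, averaged 8.81 and 11.16. Among the keratinocyte lists, 15 of 19 basal, 25 of 34 terminal differentiation, 8 of 11 stress and 4 of 6 simple keratin genes were lower in the GFP arrays (medians -0.79, -0.39, -0.19 and -0.16). Krt5, a keratin of basal epidermal cells, averaged 12.95 and 13.35, its partner Krt14 12.92 and 13.90, the transcription factor Trp63 10.19 and 11.56 and the desmosomal protein Dsp 11.71 and 12.75. The difference between the 3' and 5' control probe sets of Gapdh, which grows as labelled RNA shortens, was 3.193 and 3.189 in the GFP arrays and between -0.043 and 0.062 in the others. Because the tag marks 1 array of each tumour type, values with the tag as a covariate and values within the GFP pair stand beside Nr2f2, Xist, Slit2, the called lists and the endothelial and fibroblast markers below.

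**Figure D1:**
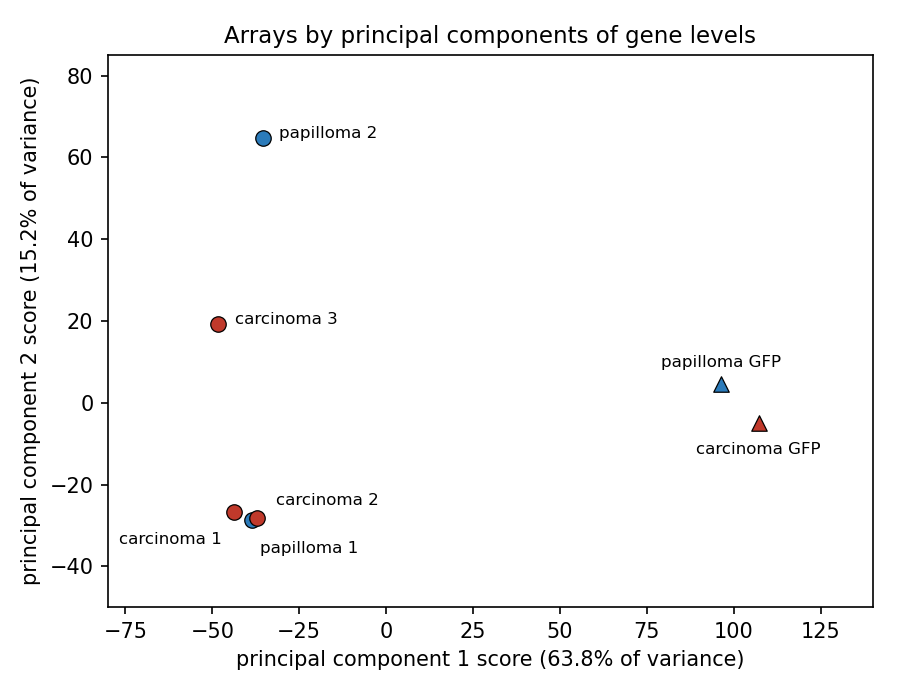
Scores of the 7 arrays on the first and second principal components of the gene-level log2 values, with papilloma in blue, carcinoma in red and triangles for the arrays labelled GFP. Carcinoma GFP and papilloma GFP sit at 107.1 and 96.3 on the first component, and the other 5 arrays sit between -48.3 and -35.5.

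Nr2f2 averaged 8.58 ± 0.67 (SD, n = 4) in carcinoma cells and 7.36 ± 1.08 (SD, n = 3) in papilloma cells on its brightest probe set, 1416159_at, a difference of 1.22 log2 units (SE 0.57). The difference did not pass the threshold over all genes (limma adjusted p = 1), and an exact two-sided permutation test of this gene alone gave p = 0.171, where 0.0571 is the smallest value that 4 against 3 arrays allow and the replicate numbers are ignored. Within the pairs of arrays numbered 1, numbered 2 and labelled GFP the difference was 1.96, 1.95 and 0.58 (exact sign-flip p = 0.25, the smallest that 3 pairs allow), and with the replicate block it was 1.50 (SE 0.34, limma adjusted p = 0.999). The level in papilloma GFP, 8.54, lay above those of carcinoma 2, 8.35, and carcinoma 3, 7.74. With the GFP tag as a covariate the difference was 1.32 (SE 0.40), and among the arrays without the tag it was 1.62 (SE 0.46). The 6 probe sets of Nr2f2 differed among themselves: 1416158_at gave 1.16, 1416160_at 0.59 and 1436475_at 0.55, whereas the dim probe sets 1431237_at and 1444229_at gave -0.02 and -0.14. Averaging all 6 reduced the difference to 0.56, and leaving out papilloma 2 reduced it to 0.73. On 1416158_at, 1416160_at and 1436475_at both GFP arrays lay above every other array. Carcinoma GFP and papilloma GFP had 7.48 and 7.13 on 1416160_at, against 3.82 to 5.73 in the others. On 1436475_at they had 7.36 and 7.05, against 4.26 to 5.86. Whether the Nr2f2 signal of the GFP arrays came from tumour cells or from other cells was not tested.

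The sorting antigens were bright in both tumour types. Cd34 averaged 10.41 ± 0.90 (SD, n = 4) in carcinoma and 10.41 ± 1.49 (SD, n = 3) in papilloma cells. Its level also followed the GFP tag, at 11.73 in carcinoma GFP and 11.66 in papilloma GFP, against 8.76 to 10.80 in the other arrays. Whether that signal came from tumour cells was not tested. Epcam averaged 11.01 ± 1.02 (SD, n = 4) and 10.26 ± 1.86 (SD, n = 3), a difference of 0.76 (SE 0.93, limma adjusted p = 1). Leaving out papilloma GFP, where Epcam was lowest at 8.28, turned the difference to -0.23. These are values of its brightest probe set. On 1447899_x_at, of the kind prone to cross-hybridisation, the tumour types differed by 0.06. That probe set gave 8.70 in carcinoma GFP and 7.79 in papilloma GFP, against 8.02 to 9.04 in the other arrays.

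**Figure D2:**
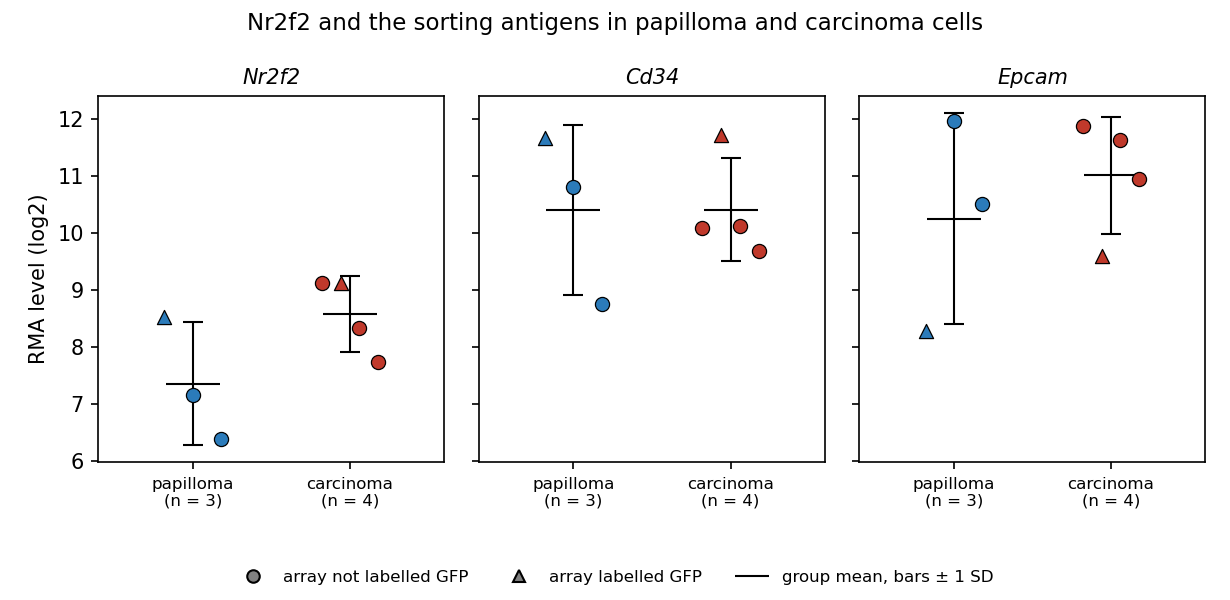
RMA levels on the log2 scale of Nr2f2, Cd34 and Epcam in each array, with papilloma (n = 3) in blue, carcinoma (n = 4) in red, triangles for the arrays labelled GFP, and horizontal lines and bars for the group mean ± 1 SD. Nr2f2 averaged 8.58 in carcinoma and 7.36 in papilloma cells, with papilloma GFP at 8.54 inside the carcinoma range.

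Among 18193 genes, the lowest p-values belonged to Xist, the RNA that silences one X chromosome in female cells, and Slit2, a secreted ligand of Robo receptors. Xist averaged 6.53 ± 0.83 (SD, n = 4) in carcinoma and 10.42 ± 1.14 (SD, n = 3) in papilloma cells, a difference of -3.89 (SE 0.64). For this RNA of female cells, a different share of such cells cannot be told apart from an effect of the tumour type. Slit2 averaged 8.10 ± 0.75 (SD, n = 4) in carcinoma and 5.76 ± 0.68 (SD, n = 3) in papilloma cells, a difference of 2.34 (SE 0.49). Within the GFP pair the differences were -2.75 for Xist and 2.14 for Slit2, and with the tag as a covariate they were -3.81 (SE 0.56) and 2.42 (SE 0.38). Neither passed the threshold after adjustment, and no other gene did: limma called 0 genes higher and 0 lower at an adjusted p of 0.05, and the smallest adjusted p was 1. At an unadjusted p under 0.05 there were 112 genes, 59 higher and 53 lower, where 909.65 are expected by chance. With the GFP tag as a covariate 331 genes had such a p, without the GFP arrays 308, and with the replicate block 500, and each of these fits also called 0 genes. In simulated arrays with this spread the test recovered 0 of 200 genes changed by 1 log2 unit and 144 of 200 changed by 2 units. The simulated genes were independent and 200 changed at once, so these shares need not hold for the real arrays.

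The other genes named by rule did not pass the threshold (limma adjusted p = 1 for each) and are those with the smallest unadjusted p in each direction whose groups did not overlap. Groups did not overlap for 258 genes, 92 with carcinoma above and 166 with carcinoma below, where chance gives 5.71% of genes or 1039.6. Among the secreted and matrix proteins, Fbln2, an extracellular matrix protein, differed by 1.46 (SE 0.53) and Ctsl, a lysosomal cysteine protease, by 0.67 (SE 0.20). Arg1, the arginase of the urea cycle, differed by 1.20 (SE 0.37), from 6.77 ± 0.72 (SD, n = 3) in papilloma to 7.97 ± 0.37 (SD, n = 4) in carcinoma cells. Gfpt1, which controls entry into the hexosamine pathway, differed by 0.55 (SE 0.19), and Cul1, the scaffold of a ubiquitin ligase, by 0.68 (SE 0.24). Differences for Avl9, Stk17b, Fam102b, Fbxo3, Tmem168, Fuca2, Snx24 and Zfp62 lay between 0.45 and 0.80.

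Genes with lower carcinoma means, also short of the threshold (limma adjusted p = 1 for each), followed the same rule. Ndufb10, Ndufs8, Ndufv2 and Ndufa8, subunits of respiratory complex I, differed by -0.76 (SE 0.22), -0.42 (SE 0.15), -0.56 (SE 0.20) and -0.43 (SE 0.18). Atp5k, a subunit of ATP synthase, differed by -0.59 (SE 0.19), and Mrpl41, a protein of the mitochondrial ribosome, by -0.75 (SE 0.18). Smox, the spermine oxidase, differed by -0.72 (SE 0.27) and Nrtn, a neurotrophic factor, by -0.51 (SE 0.18). Otud7a, a deubiquitinase, differed by -1.48 (SE 0.55). Differences for Smim4, Smim26, Mkks and Pigx lay between -0.75 and -0.44.

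Of 27 gene lists, 2 ranked higher and 1 ranked lower in carcinoma cells than the other genes of the array, by limma's camera test with a preset correlation. The basal keratinocyte and hemidesmosome list had 17 of 19 measured genes with a higher carcinoma mean and a median difference of 0.38 (camera adjusted p = 0.000107, and adjusted p = 0.953 with an estimated correlation). Col17a1, a hemidesmosomal collagen, averaged 12.11 in carcinoma (n = 4) and 11.09 in papilloma cells (n = 3), a difference of 1.02 (SE 0.64). The laminin chains Lamb3 and Lama3 differed by 0.96 (SE 0.68) and 0.87 (SE 0.63), and Dst, a linker of keratin filaments to hemidesmosomes, by 0.93 (SE 0.51). The keratins Krt5 and Krt14 differed by 0.05 and 0.08, and Krt15 by -0.47. None of the 19 members passed the threshold over all genes, nor when adjusted over the list alone (0 and 0). In the GFP arrays the list lay lower than in the other arrays by a median of -0.79, and within the GFP pair its median difference between the tumour types was 0.04. With the GFP tag as a covariate the median was 0.35 (camera adjusted p = 0.000875, and adjusted p = 0.884 with an estimated correlation). The call ended with the replicate block (median 0.33, adjusted p = 0.0509) and without papilloma GFP (0.28, adjusted p = 0.0568), and without papilloma 1 the median was 0.68.

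The list of epithelial junction and identity genes had 27 of 31 measured members with a higher carcinoma mean and a median difference of 0.27 (camera adjusted p = 0.00515, and adjusted p = 0.953 with an estimated correlation). The desmosomal cadherins Dsc2 and Dsg2 differed by 1.05 (SE 0.76) and 0.80 (SE 0.83), the tight junction protein Cldn4 by 0.92 (SE 1.11), and Ehf, an epithelial transcription factor, by 0.91 (SE 0.69). Of its members 0 passed over all genes and 0 adjusted over the list alone. This list was lower in the GFP arrays by a median of -1.30, within the GFP pair its median was 0.04, and with the tag as a covariate it was 0.16 (camera adjusted p = 0.00884, and adjusted p = 0.884 with an estimated correlation). Its call ended without carcinoma 1 (median 0.09, adjusted p = 0.573), without carcinoma 2 (0.16, adjusted p = 0.103) and without papilloma GFP (-0.13, adjusted p = 0.741), and the median was 0.61 without carcinoma GFP, 0.66 without papilloma 1 and 0.17 without both GFP arrays.

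Genes of the interferon response and antigen presentation ranked lower in carcinoma cells, with 22 of 28 measured members at a lower mean and a median difference of -0.34 (camera adjusted p = 0.000212, and adjusted p = 0.953 with an estimated correlation). Psmb8 and Psmb9, subunits of the immunoproteasome, differed by -1.99 (SE 0.83) and -1.54 (SE 0.75). Tap1, part of the peptide transporter for class I molecules, averaged 7.50 ± 0.86 (SD, n = 4) in carcinoma and 8.61 ± 0.39 (SD, n = 3) in papilloma cells, and Gbp2, an interferon-induced GTPase, averaged 6.61 ± 2.85 (SD, n = 4) and 8.66 ± 1.07 (SD, n = 3). Members at a higher carcinoma mean included Ddx58, a sensor of viral RNA, at 0.31, and Mx1, an antiviral GTPase, at 0.24. Over all genes 0 members passed, and adjusted over the list alone 0. The list was higher in the GFP arrays by a median of 1.02, and within the GFP pair its median was 0.13, with the carcinoma array above the papilloma array, against -0.25 with the tag as a covariate (camera adjusted p = 0.0015, and adjusted p = 0.884 with an estimated correlation). Its call ended without carcinoma 1 (median -0.08, adjusted p = 0.076), without carcinoma 2 (-0.27, adjusted p = 0.0623) and without papilloma GFP (-0.06, adjusted p = 0.543), and the median was -0.58 without carcinoma GFP and -0.59 without papilloma 1.

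**Figure D3:**
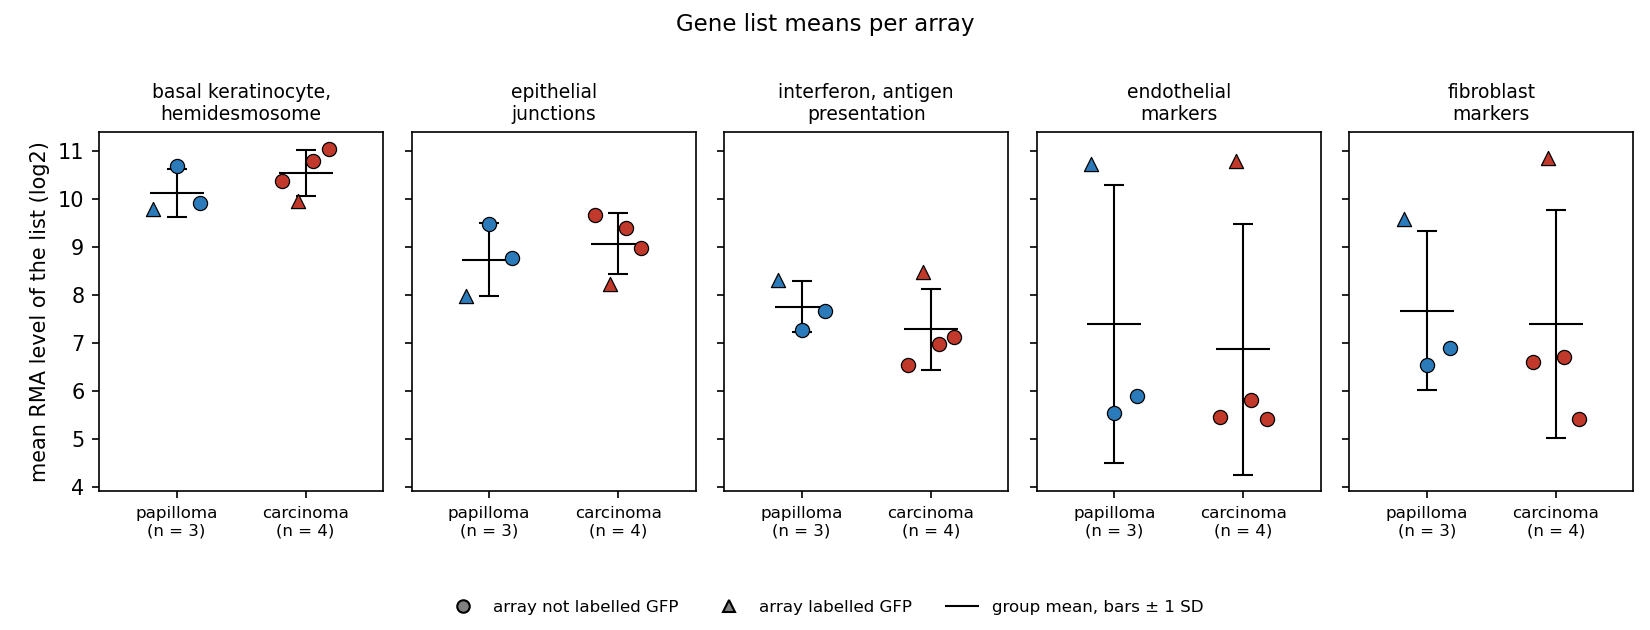
Mean RMA level on the log2 scale of 5 gene lists in each array, with papilloma (n = 3) in blue, carcinoma (n = 4) in red, triangles for the arrays labelled GFP, and horizontal lines and bars for the group mean ± 1 SD. Endothelial list means were 10.79 and 10.73 in the GFP arrays and between 5.41 and 5.90 in the others, and the basal keratinocyte list averaged 10.54 in carcinoma and 10.12 in papilloma cells.

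The lists closest to the title of the series did not pass the test with all 7 arrays. Matrix protease and invasion genes had a median difference of 0.27 (17 of 26 genes higher, camera adjusted p = 0.0712), with Mmp12, a metalloelastase, at 1.32 (SE 0.66) and Timp3, a protease inhibitor, at -1.06 (SE 1.11). The Mmp12 difference rested on dim levels of 4.10 in papilloma GFP and 4.09 in papilloma 2. In papilloma 1 Mmp12 lay at 6.64, above the carcinoma arrays, at 5.64 to 6.61. Stem cell and progenitor factors of squamous carcinoma had a median of 0.23 (19 of 28 genes higher, camera adjusted p = 0.0712), with Sox2, a stem cell transcription factor, at 8.02 ± 2.16 (SD, n = 4) in carcinoma and 5.56 ± 1.56 (SD, n = 3) in papilloma cells, and Pitx1 at 1.40 in carcinoma minus papilloma. With the GFP tag as a covariate both lists passed (camera adjusted p = 0.00883 and 0.0118, and adjusted p = 0.884 with an estimated correlation), but without the GFP arrays neither did (0.182 and 0.112). Leaving out 1 array turned the protease median to -0.10 without carcinoma GFP and -0.04 without papilloma 2, moved it to 0.125 without carcinoma 2, and called the list higher without carcinoma 1 (adjusted p = 0.0032), carcinoma 3 (0.00172) or papilloma GFP (0.0128). The stem cell median fell to 0.13 without carcinoma 1, 0.09 without carcinoma GFP and 0.10 without papilloma 2, and the list was called without carcinoma 3 (0.00372). Terminal differentiation genes of keratinocytes had a median of 0.07 (camera adjusted p = 0.416) and were called higher with array weights (0.0139) and without carcinoma 3 (0.0296), with a median of -0.03 without carcinoma 2, although Krt1 and Krt10, the keratins of differentiating layers, differed by -2.53 (SE 1.08) and -1.39 (SE 0.65). Mesenchymal transition genes had a median of -0.08 and a mean of -0.09 while the test pointed upward (camera adjusted p = 0.791), with Twist1, a mesenchymal transcription factor, at 1.22 (SE 0.61) and Postn, a matrix protein, at -1.32. In the GFP arrays the mesenchymal list lay higher by a median of 2.27. It was called lower without carcinoma GFP (median -0.44, adjusted p = 0.00454) and higher without papilloma GFP (median 0.51, adjusted p = 0.0128).

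With the replicate block, which leaves carcinoma 3 without a partner, camera called 8 lists higher and 3 lower in place of 2 and 1. It called the junction list (adjusted p = 1.89e-05), the matrix protease list and the stem cell list (both 5.83e-05), myeloid markers (0.000267), mesenchymal transition genes (0.00328, median 0.25), simple epithelial keratins and fibroblast markers (both 0.026) and lipid synthesis genes (0.0464) higher. Lower were the interferon list (1.89e-05), melanocyte markers (0.0143) and immediate early genes (0.0412, median -0.13). The smallest adjusted p with an estimated correlation was 0.626 in this fit.

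The other lists of tumour cell biology did not pass with all 7 arrays. Simple epithelial keratins had a median of 0.06 (camera adjusted p = 0.238), with Krt18 at 2.30 (SE 1.08) and Krt8 at 1.65 (SE 0.86). Stress keratinocyte genes had a median of 0.04 but a mean of -0.53 and a downward test (camera adjusted p = 0.238), with the calprotectin subunits S100a8 and S100a9 at -2.44 and -1.72. The cytokine list had a median of -0.0013 (camera adjusted p = 0.929), with Tslp, an epithelial cytokine, at 6.97 ± 1.90 (SD, n = 4) in carcinoma and 10.07 ± 1.78 (SD, n = 3) in papilloma cells, and Csf3 at 1.14. Hair follicle genes had a median of -0.11 (0.29), with Lhx2, a hair follicle stem cell factor, at -1.61. Lhx2 was dim, at 4.12 to 5.19 in the carcinoma arrays, and papilloma GFP lay inside that range at 5.02. Cell division genes had a median of 0.11 (0.117), with Cenpe at 0.70 and Mki67 at 0.61, and glycolysis and hypoxia genes a median of 0.03 (0.117), with Adm at 1.03 and Ndrg1 at 0.65. Genes responsive to transforming growth factor beta had a median of 0.14 (0.317), with Tgfb2 at -1.17 and Tgif1 at 0.68, and Notch pathway genes a median of -0.11 (0.734), with Nrarp at -0.83 and Mfng at -0.58. Wnt pathway genes had a median of 0.02 (0.574), with Wif1 at -1.14 and Dkk3 at 0.68, and lipid synthesis genes a median of 0.06 (0.347), with Acsbg1 at 1.46 and Scd1 at -0.84. Wif1 lay near background in carcinoma 1, carcinoma 2 and carcinoma 3, at 3.21 to 3.47, so the size of its difference is uncertain. Oxidative stress genes had a median of -0.01 (0.929), with Gstm5 at -0.91 and Cyp1b1 at 0.62. Immediate early genes, which respond to cell isolation, had a median of 0.02, a mean of -0.05 and a downward test (0.791), with Egr2 at -1.22 and Junb at -0.42. Each of these lists except glycolysis and hypoxia had a median of the other sign when some 1 array was left out. Calls also appeared in this way. Cell division genes were called higher without carcinoma GFP (median 0.24, adjusted p = 0.00196) and papilloma 1 (0.33, adjusted p = 2.9e-05), against -0.10 without papilloma GFP. Glycolysis and hypoxia genes were called higher without carcinoma 1 (0.15, adjusted p = 0.0346), carcinoma GFP (0.15, adjusted p = 0.028) and papilloma 1 (0.29, adjusted p = 0.00029). Simple epithelial keratins and lipid synthesis genes were called higher without carcinoma 3 (0.17 and 0.20, both adjusted p = 0.0296), stress keratinocyte genes lower without carcinoma 2 (-0.30, adjusted p = 0.00986) and Notch genes lower without carcinoma GFP (-0.21, adjusted p = 0.028).

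Markers of other cell types were compared in the same way. Endothelial markers had lower carcinoma means for 15 of 15 genes and a median of -0.52 (camera adjusted p = 0.29), with Ramp2 at -0.82 and Plvap at -0.73. The GFP arrays, where these markers are high, are 1 of 3 papilloma and 1 of 4 carcinoma arrays, which alone lowers the carcinoma mean. With the tag as a covariate the endothelial median was -0.15 with 4 of 15 genes higher, within the GFP pair it was 0.11, and without papilloma GFP the list was called higher (median 1.20, camera adjusted p = 0.0128), but it was called lower without carcinoma GFP (-1.96, adjusted p = 1.53e-05), papilloma 1 (-1.51, adjusted p = 0.00796) or papilloma 2 (-1.30, adjusted p = 0.0286) and with array weights (-0.85, adjusted p = 0.0451). Fibroblast markers had a median of -0.35 (0.929), with Dpt at -1.04 and Lum at -0.95, against -0.02 with the tag as a covariate, -0.56 without the GFP arrays, 0.48 with the replicate block and 1.22 within the GFP pair. The fibroblast list was called lower without carcinoma GFP (median -1.66, adjusted p = 0.000164), and without papilloma GFP its median was 0.65 (adjusted p = 0.0852). Langerhans and dendritic cell markers had a median of -0.11 (0.238), with the class II genes H2-Aa and H2-Ab1 at -1.09 and -0.79. Myeloid markers had a median of 0.06 (0.416), with Cd14 at 0.36 and Cd68 at 0.35. Lymphocyte markers had a median of 0.01, a mean of -0.04 and a downward test (0.791), with Cd8a at -0.40 and Cd3d at -0.31. Melanocyte markers had a median of -0.18 (0.0712), with Dct at -0.76 and Tyrp1 at -0.68. Muscle and adipocyte markers had a median of 0.03 (0.791), with Fabp4 at -0.49 and Tnni2 at 0.44, and red blood cell markers a median of -0.19 (0.29), with Alas2 at -0.38 and Slc4a1 at -0.33. Without carcinoma GFP the Langerhans (median -0.34, adjusted p = 0.00175), lymphocyte (-0.21, adjusted p = 0.0162) and melanocyte lists (-0.30, adjusted p = 0.0112) were called lower, as were the Langerhans (-0.39, adjusted p = 0.00796) and melanocyte lists (-0.35, adjusted p = 0.000557) without papilloma 1. With other single arrays left out the camera adjusted p rose to 0.795 for the Langerhans list and 0.817 for the melanocyte list. The Langerhans test kept its direction in 17 of 18 alternatives. Myeloid markers were called higher without papilloma GFP (0.39, adjusted p = 0.0128) and carcinoma 3 (0.34, adjusted p = 0.00999), against -0.19 without carcinoma GFP. In the GFP arrays Langerhans and myeloid markers lay higher by medians of 1.11 and 1.27. No member of any of the 27 lists passed the threshold over all genes or adjusted over the list alone (0 and 0), and with an estimated correlation camera called 0 lists.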

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

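The tests on the GFP arrays and on Xist were chosen after the results were seen. The counts over other splits of the arrays were planned before, except those over splits that part the GFP arrays, which were added afterwards. An array was marked when its gap to the nearest carcinoma array took an unusually large share of the range of the 4 carcinoma arrays (Dixon's criterion), which chance does in about 1 of 20 measures, and 11 of 119 measures were marked. Papilloma, with 3 arrays, was not tested in this way.

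Carcinoma GFP stood apart for Wif1, at 7.68 against 3.21 to 3.47 in the other carcinoma arrays (share 0.942), Mfng at 9.17 against 5.49 to 5.77 (0.925), Ramp2 at 10.94 against 4.69 to 5.42 (0.882) and Cd3d at 6.12 against 4.73 to 4.77 (0.972). For Wif1 those other arrays lay near background, since control probe sets for a bacterial transcript had medians of 3.30 to 3.43 in them. The exact Wif1 gap is therefore uncertain. Carcinoma GFP also stood apart for Cldn4 at 6.95 against 10.15 to 10.45 (0.914) and Tgif1 at 7.51 against 9.98 to 10.36 (0.869). The mean of the endothelial markers was 10.79 there against 5.41 to 5.81 (0.925). The differences between 3' and 5' control probe sets were 3.19 against -0.02 to 0.06 for Gapdh (0.975) and 2.21 against 0.51 to 0.77 for beta-actin (0.849). Carcinoma 3 stood apart in the mean of the hair follicle list, at 7.18 against 7.64 to 7.71 (0.865).

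Papilloma GFP shared the endothelial mean, at 10.73, and the control differences, at 3.19 for Gapdh and 2.58 for beta-actin, but not Wif1, at 5.43 between papilloma 1 and papilloma 2, so the 2 GFP arrays were weighed as a pair against the other 5. RNA quality alone would leave endothelial markers near other genes, but their median was 5.31 log2 units higher, and a mesenchymal state of the tumour cells alone would leave endothelium-restricted genes low, but 15 of 15 markers were higher by more than 2 units. RNA of endothelial cells and fibroblasts may be part of the GFP arrays. The lower of the 2 list medians was 4.05, with Col3a1 at 13.36 against 9.08, Col1a1 at 12.11 against 7.34 and Plvap at 12.91 against 6.46. A gate on Epcam should remove such cells, but Epcam on its brightest probe set averaged 8.94 in the GFP arrays against 11.39. Cd34, the other sorting antigen, averaged 11.69 against 9.89. Kdr is also in the list of stem cell factors, and 0 of 15 endothelial markers overlapped between the GFP arrays and the others. A contribution of shorter RNA stays open, since the control probe sets differed too, and an effect of what the tag marks was not tested.

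Xist was marked for carcinoma GFP, at 7.77 against 6.07 to 6.17 in the other carcinoma arrays (share 0.937), and it was lower in all 4 carcinoma arrays than in the papilloma arrays, which lay between 9.23 and 11.50 (exact two-sided permutation p = 0.0571, the smallest that these arrays allow, or 0.25 over the 3 pairs, also the smallest). A split of the sexes between the tumour types would leave the Y-linked gene Eif2s3y below the carcinoma arrays in every papilloma array, but it reached 9.45 in papilloma 1, above all 4 carcinoma arrays. Male and female cells together may be in papilloma 1 and papilloma GFP, which had both Xist and Eif2s3y, the lowest Xist level of the 2 being 9.23. Papilloma 2 had the highest Xist level, 11.50. There the Y-linked genes Eif2s3y, Kdm5d and Uty lay at 3.56, 3.80 and 3.40 on their brightest probe sets. Control probe sets for a bacterial transcript had a median of 3.41 in that array. Carcinoma 1 had Eif2s3y at 6.53, so the carcinoma arrays differed too. Its Xist level was 6.07, the lowest of the 4 on the brightest probe set. The lower Eif2s3y there thus came without higher Xist, and its cause was not tested. If Xist shows the share of female cells, that share cannot be told apart from the tumour type for any gene compared here. Expression of Xist in male tumour cells was not tested and stays open.

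The comparison itself was set against the other splits of the 7 arrays into 4 and 3. A count of 0 called genes, as in the real split, is reached by any split (35 of 35), so it says nothing about chance. The highest other split, the GFP pair with papilloma 2 against the rest, gave 164, which points to the structure of the samples. At an unadjusted p under 0.05, 30 of 35 splits gave at least the 112 genes of the real split, with 4009 as the highest other. At least 3 gene lists were called in 31 of 35 splits, with 16 as the highest other. Both highest counts came from splits with both GFP arrays on one side, which measure the tag. Of the 20 splits that part the GFP arrays, 15 gave at least 112 genes, with 1358 as the highest other. At least 3 lists were called in 16 of these 20, with 11 as the highest other. Chance cannot be excluded for the genes at an unadjusted p or for the lists. With the replicate block the real split called 11 lists and the highest other split 7, and the 4 distinct splits that part the same pairs, of which 1 reached 11, are too few for a share under 5%.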

How the results depend on the processing

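Removal of carcinoma 2 and papilloma 1 was chosen after seeing the data. Called genes stayed at 0 in each direction under every alternative, with between 49 (dim genes left out) and 560 genes (without papilloma 1) at an unadjusted p under 0.05, and each of 18 alternatives kept Nr2f2 higher in carcinoma and short of the threshold, at 0.56 to 1.80 (limma adjusted p from 0.999 to 1). Single probe sets are not among these 18, and 2 dim ones of Nr2f2 gave -0.02 and -0.14. The calls of gene lists moved with the settings, from 2 higher and 1 lower to 0 and 0 with an estimated correlation and 0 and 0 with fry, where the estimated correlations of the 3 called lists were 0.36, 0.54 and 0.48. The replicate block gave 8 higher and 3 lower, lost the basal keratinocyte list and changed no call of a gene, the GFP tag as a covariate gave 4 higher, the mean of all probe sets gave 2 lower, array weights gave 3 higher and 2 lower, and the fit without carcinoma 2 and papilloma 1 gave 4 higher and 3 lower; the cause was not tested. Leaving out each array in turn gave 1 to 8 lists higher (1 without carcinoma 2 and 8 without carcinoma 3) and 0 to 8 lower (0 without carcinoma 1 or papilloma GFP and 8 without carcinoma GFP). Of 1613 values of named genes under the alternatives, 25 reversed, in 16 genes, 0 past the threshold. Cd34, at 0.0022 with all arrays, became -0.10 after quantile normalization and -0.40 with array weights. Cd8a became 0.25 without probe sets prone to cross-hybridisation, where another probe set stands for the gene. Fabp4 became 0.63 with array weights and 0.69 with the replicate block, and Plvap 0.20 with the block. Leaving out each array in turn gave ranges across 0 of -0.82 to 0.63 for Cd34, -0.28 to 1.04 for Cyp1b1, -0.23 to 1.62 for Epcam, -0.0093 to 1.30 for Dsg2, -0.39 to 1.36 for Tgif1, -1.46 to 0.73 for Mfng, -2.27 to 0.93 for Ramp2, -2.37 to 1.36 for Plvap, -2.36 to 0.50 for Dpt, -2.21 to 0.13 for Lum, -0.73 to 0.24 for Alas2, -0.11 to 1.08 for Mki67, -0.10 to 0.99 for Cd14, -0.054 to 0.81 for Cd68, -0.66 to 0.01 for Cd8a and -1.27 to 0.69 for Fabp4. Of the 90 named genes, 16 had such ranges and 41 others, Nr2f2 included, moved by over 1.5 times without crossing 0. Of these, 14 fell by over 3 times, with ranges of 0.23 to 1.72 for Adm, -0.65 to -0.031 for Cd3d, 0.16 to 1.24 for Cenpe, 0.23 to 1.89 for Cldn4, 0.21 to 1.57 for Ehf, -1.49 to -0.15 for H2-Ab1, 0.14 to 0.98 for Ndrg1, -1.31 to -0.27 for Nrarp, 0.47 to 2.50 for Pitx1, -2.42 to -0.35 for Postn, -2.30 to -0.39 for Tgfb2, -1.95 to -0.35 for Timp3, 0.043 to 0.75 for Tnni2 and -1.25 to -0.022 for Tyrp1. Fbln2 ranged from 0.80 to 1.82 and Csf3 from 0.39 to 2.46. Also among the 41, Gbp2 ranged from -3.46 to -1.44, Egr2 from -1.65 to -0.43, Scd1 from -1.56 to -0.43 and Wif1 from -2.22 to -0.73. Leaving out the GFP arrays or any papilloma array leaves 2 papilloma arrays. Signal over background limits dim genes, since control probe sets for a bacterial transcript had medians of 3.30 to 3.47.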

Other observations

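The tests of the most alike pair of arrays were chosen after the result was seen; those of the mitochondrial genes were set before their values were computed, after the family had been noticed among the lowest p-values, except for the count over splits that part the GFP arrays, which was added afterwards. Families were taken by the stems of their gene symbols, and the genes seen among the lowest p-values were left out. Of 69 further respiratory chain genes, 63 had a lower carcinoma mean, with a median difference of -0.26, and of 75 further mitochondrial ribosome genes, 65 did, with a median of -0.17. With the GFP tag as a covariate the medians were -0.30 and -0.23, after quantile normalization -0.26 and -0.22, and after centring of the arrays -0.24 and -0.15. Camera with a preset correlation gave adjusted p = 2.31e-12 and 4.22e-07, and with an estimated correlation adjusted p = 0.255 and 0.486. Single arrays moved these values: without papilloma 2, which lay at 64.8 on the second principal component, the medians were -0.10 and -0.03, without carcinoma GFP -0.16 and 0.01, without papilloma 1 -0.25 and -0.06, without papilloma GFP -0.36 and -0.43, without carcinoma 1 -0.29 and -0.28, without carcinoma 2 -0.27 and -0.27, and without carcinoma 3 -0.31 and -0.17. The respiratory chain median was below 0 in 14 of the 15 splits with papilloma 2 in the group of 3, and in 4 of the 20 others, and the mitochondrial ribosome median in 10 and 7.

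A lower expression of the mitochondrial gene families as a whole was a hypothesis. Over the 144 genes together the median was -0.20 with 128 lower, but 9 of the 35 splits of the arrays gave a median as low, and the lowest other split gave -0.49. By the bound set before for this count, 5% of the splits, the hypothesis failed. That bound was a poor one, because 15 of the 35 splits put both GFP arrays on one side and so measure the tag. Of the 9 splits, 7 are among these. Of the 20 splits that part the GFP arrays 2 were as low, the real one at -0.203 and another at -0.205. For each family alone the real split was lowest (-0.262 against -0.254, and -0.172 against -0.139). However, 20 splits are too few for a share under 5%, so this later count cannot decide. The hypothesis did not pass its own bound and is otherwise open. Genes of the cytosolic ribosome, which are short and abundant too, had a median of -0.062 (38 of 56 lower), between the 2 values that would have decided whether short abundant transcripts shift in general, so that explanation cannot be told apart from one specific to mitochondria.

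Papilloma 1 and carcinoma 2, of different tumour types, were the most alike pair of arrays. Across genes, which are not independent replicates, their levels correlated at 0.992 with an SD of the differences of 0.30 log2 units, where the next smallest SD was 0.42 for the GFP pair. One labelled RNA hybridised on both arrays would leave only noise between them, but of 57 genes that differed by over 1 log2 unit and had another bright probe set, 55 (96.5%, exact 95% interval 87.9 to 99.6) agreed in sign on it. Because probe sets of 1 gene read the same labelled RNA, this count cannot exclude 1 RNA that was amplified separately for each array. Xist differed by 3.13 and Slit2 by -1.87 in papilloma 1 minus carcinoma 2. On its other probe sets Xist was also higher in papilloma 1, at 7.11 against 3.85 and 6.99 against 4.19. A wrong tumour type on 1 of the arrays may also give such a pair and cannot be told apart from biology here: papilloma 1 differed from papilloma 2 with an SD of 0.73, against 0.52 for carcinoma 1 and 0.63 for carcinoma 3, but papilloma 2 lay far from every array and papilloma has only 1 other array without the tag.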
